A study of Mus musculus with 13 samples.

How the data were processed

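The series holds 13 arrays in 4 groups, given here by genotype and state, with 2 wild-type naive, 3 Batf-/- naive, 4 wild-type day 3 and 4 Batf-/- day 3 arrays. Per the labels' protocols, P14 CD8+ T cells were isolated by magnetic negative selection, which removes marked cells of other types and leaves CD8+ T cells untouched, and were stimulated with plate-bound antibodies in the presence of IL-2. RNA was labelled with biotin. The values are probe set intensities, which were summarised with RMA, per the submitters' processing notes. RMA corrects the background, normalises the arrays to each other and combines the probes of a set. No version is given. The deposited intensity values are above 0 and reach 27465, with medians from 31.5 to 32.5 in all arrays, so they are on a linear scale. They were converted to log2 here, and the arrays were not normalised again. Lower quartiles lay between 10.8 and 11.4 and upper quartiles between 159 and 173. The log2 difference between the 3' and 5' probe sets was between -0.081 and 0.099 for Gapdh and between 0.265 and 0.433 for actin.

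The table held 45101 probe sets. Of these, 34958 are assigned to 1 gene, 932 to several genes and 9211 to none, and 64 of the 45101 are control probe sets. Gene names came from the platform table, and 34754 of its gene identifiers were found in the RefSeq gene table of assembly GRCm38.p6, where 0 symbols differed. For each of the resulting 18194 genes the probe set with the highest mean over the 13 arrays was used, which involved a choice for 9012 genes. No filter on dim probe sets was applied. The lowest 40% of probe sets, referred to as dim or near the background, had mean log2 intensities below 4.72. Where the mean of a group lies below that value, differences from it are in measured intensity and are read as lower bounds of the change in RNA.

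Linear models with 4 group means were fitted to all 13 arrays with limma 3.58.1 in R 4.3.3, with the spread moderated by eBayes (9 residual and 3.702 prior degrees of freedom). The 5 contrasts were Batf-/- minus wild type at day 3, Batf-/- minus wild type in naive cells, day 3 minus naive in each genotype, and the difference between the latter. Tests were two-sided moderated tests with Benjamini-Hochberg adjustment over the genes of a contrast, and an adjusted p below 0.05 counts as passed. Rises and falls are log2 differences with their standard error. The labels do not state whether the arrays of a group come from separate animals or cultures, so the p-values measure the spread between arrays. That spread is pooled over the 4 groups, and naive arrays differed more from each other than day 3 arrays did. The pooled spread therefore tends to be too small for the naive comparison, whose p-values may be too low, and too large for the day 3 comparison.

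Named genes followed a rule. For each contrast it takes the 12 largest increases and the 12 largest decreases among genes that passed and whose groups did not overlap (overlap was not asked of the interaction), without clone and model names. It also takes Batf and members of the fixed lists as examples, those with the largest change or against the direction of their list. A total of 31 program lists and 11 lists of markers for other cell types were fixed, with 599 of 658 genes measured. Lists of at least 5 measured genes were tested, which left out the lists for gamma delta T cells and erythroid cells. The lists were tested with camera, with a preset correlation between genes of 0.01, and adjusted separately over the program lists and the 9 cell type lists of a contrast. An estimated correlation and the directional test fry served as alternatives. The counts of members that passed use the adjustment over all genes, and counts adjusted over the list alone are given beside them. These choices, the contrasts and the alternatives were made before the data were examined.

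The share of the response was the median ratio of the Batf-/- to the wild-type change. Genes with at least a 4-fold change were chosen on wild-type day 3 replicates 1 and 2 and naive replicate 1, and their ratio was taken against the remaining wild-type arrays, and the same was done with the parts exchanged. For each pair of call lists, the number that independent lists would share is the product of their sizes divided by the number of genes tested. The calls of the 2 stimulation contrasts share no arrays, nor do those of the 2 genotype contrasts, although each fit shares the pooled estimate of the spread.

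The alternatives were another quantile normalisation, centring on the array median, leaving out the dim 40% of probe sets, the mean of all probe sets of a gene, an intensity trend or robust estimation in eBayes, array quality weights, the replicate number as a block, the compared groups alone, a minimum change of 2-fold and leaving out each array in turn.

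The analysis was tested on simulated data with 200 changed genes among 18194. These data had the wild-type means of these arrays and 1 spread per gene, pooled over the 4 groups. For the day 3 contrast 79.2% of genes changed by a log2 of 0.5 were recovered, with 100% of those changed by 1 and by 2, and 13 of 197 calls were false. For the naive contrast 48.5%, 97% and 100% were recovered at these sizes, and 7 of 171 calls were false. Of 3 lists shifted by a log2 of 0.5 all were recovered by camera with either correlation and by fry, and 0 of 28 other lists were called. Since the real naive arrays varied more than the day 3 arrays, the values for the naive contrast may be too favourable. The simulated genes varied independently of each other. The simulation therefore does not show how often lists are falsely called where their genes vary together. A simulated response share of 0.8 was estimated as 0.802.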

Results

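RNA of P14 CD8+ T cells was profiled on 13 oligonucleotide arrays. P14 mice carry a transgenic T cell receptor, so that most of their CD8+ T cells share a single specificity. The cells came from wild-type mice or from mice without Batf, a transcription factor of the AP-1 family that pairs with Jun proteins and acts with Irf4 in activated lymphocytes. They were taken as naive cells, on day 0 (2 wild-type and 3 Batf-/- arrays), or after 3 days with antibodies to CD3 and CD28 and 100 U/ml IL-2 (4 arrays of each genotype). Median intensities lay between 31.5 and 32.5 over the 13 arrays, and the number of arrays limits the precision. The principal component with the most variance (83.7%) separated naive from day 3 arrays in both genotypes.

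Batf itself was high in wild-type cells in both states and low in every Batf-/- array. Its log2 intensity was 9.19 and 9.36 in the wild-type naive arrays, and 5.60, 6.06 and 5.94 in the Batf-/- naive arrays. At day 3 it was 8.63, 8.80, 8.83 and 9.19 in wild-type arrays, and 6.77, 5.56, 5.61 and 6.00 in Batf-/- arrays. The difference was -3.41 ± 0.29 (SE, n = 3 and 2, adjusted p = 0.000321) in naive cells and -2.88 ± 0.23 (n = 4 and 4, adjusted p = 6.9e-05) at day 3.

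**Figure D1:**
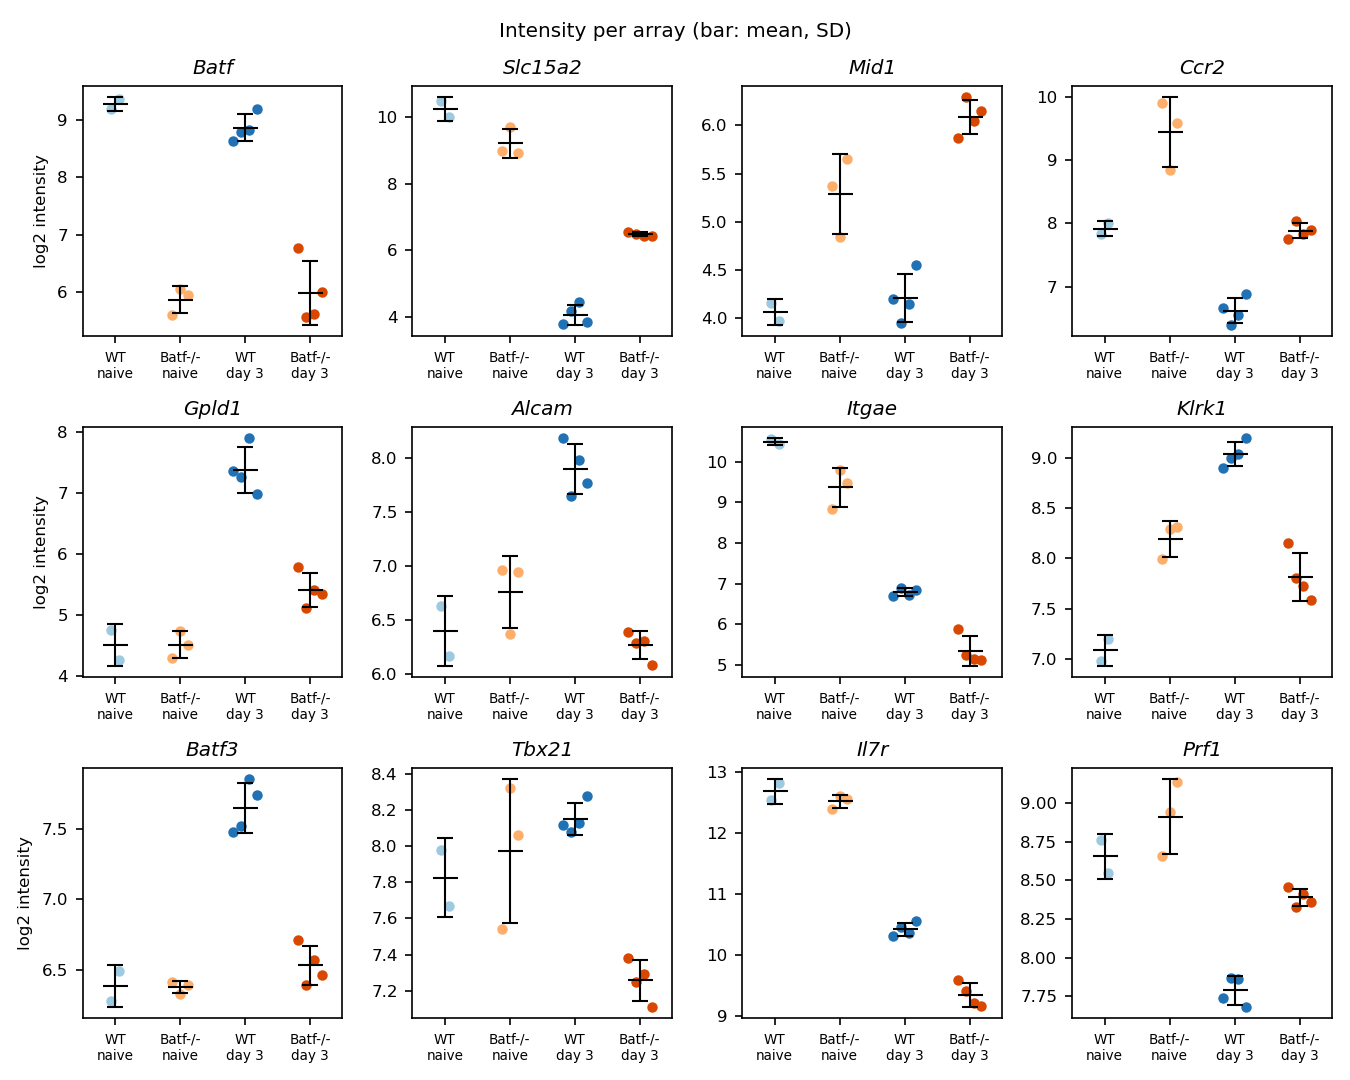
Log2 intensity of 12 genes in each of the 13 arrays, by group (points, arrays; bars, mean and SD). Batf was low in every Batf-/- array, and Klrk1 was higher than in wild type in naive Batf-/- cells but lower at day 3.

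The comparison of the genotypes at day 3 asks what stimulated CD8+ T cells express differently without Batf. Among the genes lower in stimulated Batf-/- cells were Itgae (-1.44 ± 0.20), the alpha chain of an integrin that binds E-cadherin, Havcr2 (-1.23 ± 0.17), the inhibitory receptor Tim-3, and Klrk1 (-1.22 ± 0.12), the activating receptor NKG2D. Alcam, an adhesion molecule that binds Cd6, was also lower (-1.63 ± 0.15). Batf3, the relative of Batf needed for some dendritic cells, was 2.17-fold lower (-1.12 ± 0.09, adjusted p = 7.2e-05). Among the higher genes were the peptide transporter Slc15a2 (at least 5.35-fold, 2.42 ± 0.18, adjusted p = 6.9e-05), the uridine phosphorylase Upp1 (1.35 ± 0.16) and Ccr2 (1.26 ± 0.18), a chemokine receptor that guides cells to inflamed tissue (log2 ± SE, n = 4 and 4 throughout).

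Of 18194 genes tested, 250 passed the test in this comparison, 121 higher and 129 lower in Batf-/- cells. At least a 2-fold change was seen for 30 of them, 11 higher and 19 lower. The other named genes that were higher were Mid1 (1.88), which codes for a microtubule-binding ubiquitin ligase, Erdr1 (1.63), Rpl39l (1.37), the actin regulator Enah (1.17), the receptor P2ry14 (1.09), the cytokine Tgfb3 (1.05), the lysine methyltransferase Vcpkmt (1.01), Morc1 (1.0) and Myl10 (0.99). The other named genes that were lower were Gpld1 (-1.96), which codes for a phospholipase that releases GPI-anchored proteins, thyroglobulin (Tg, -1.84), the endosomal GTPase Rab4a (-1.40), the transcription elongation factor Ell2 (-1.32), Zfp365 (-1.26) and Ctla2b (-1.26). Slc15a2, Mid1 and Morc1 in wild-type and Havcr2 in Batf-/- arrays had day 3 means near the background, so their differences are lower bounds. For the mean over all probe sets of the gene, the difference was smaller for Slc15a2 (0.84), Mid1 (0.69), Ccr2 (0.80), Enah (0.35), Ell2 (-0.68) and Zfp365 (-0.76), with the same direction, and the same holds for Ccr9 (0.42) and Prf1 (0.26), named below, of which Prf1 did not pass (adjusted p = 0.0989), nor did Lif and Fbl. Groups without any overlap between the 8 arrays were seen for 2326 genes, or 12.8%, where chance gives 2.86%.

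Genes of cytotoxic function stood higher in stimulated Batf-/- cells. Of 24 measured members, 7 rose, none fell and 17 did not pass (10 rose when adjusted over the list alone). They included the cytokine Lta (0.84), the death ligand Fasl (0.76), the granzyme inhibitor Serpinb9 (0.64) and perforin, Prf1 (0.61), the pore-forming protein of cytotoxic granules. The list median was 0.17 (camera, adjusted p = 0.000543), and the call was lost with adjusted p = 0.163 with an estimated correlation. Of 23 ribosome biogenesis genes 3 were higher, Nop56 (0.32), Utp20 (0.32) and Fbl (0.26), and 9 when adjusted over the list alone (median 0.16, adjusted p = 9.07e-08, or adjusted p = 0.329 with an estimated correlation). Of 22 type I interferon response genes 1 was higher, the exonuclease gene Isg20 (0.67), with the same count when adjusted over the list alone (median 0.14, adjusted p = 0.00369, or adjusted p = 0.698 with an estimated correlation). That interferon call was also lost without Batf-/- day 3 replicate 1 (adjusted p = 0.0932).

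Naive and memory T cell genes stood lower. Il7r, the receptor for the survival cytokine interleukin 7, was lower by the test (2.11-fold, log2 -1.075), and 19 of the 20 measured members did not pass (6 were lower when adjusted over the list alone). Id3 (-1.17) and Bcl6 (-0.83) had large differences that did not pass. The list median was -0.09 (camera, adjusted p = 0.00369, or adjusted p = 0.698 with an estimated correlation). None of the 4 list calls at day 3 held with an estimated correlation.

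Other fixed lists were not called at day 3, but single members were. T-bet (Tbx21, -0.89), the transcription factor that drives type 1 effector genes, and the Notch partner Rbpj (-0.40) were lower among 16 effector transcription factors, while Eomes was at 0.83 without passing (3 rose and 3 fell when adjusted over the list alone). Among 16 inhibitory receptors Havcr2 and Ctla4 (-0.71) were lower (3 higher and 5 lower when adjusted over the list alone). Among 17 costimulatory receptors Tnfrsf4, or OX40 (-1.04), and Icos (-0.40) were lower and Tnfsf8 (0.40) was higher. Among 23 chemokine receptors and homing molecules Ccr2 and the gut-homing receptor Ccr9 (0.84) were higher, and Itgae and Cxcr6 (-1.0) were lower. The cytokine genes Lif (0.75) and Osm (0.46) and the phosphatase gene Dusp1 (0.48) were higher, and Dusp4 (-0.55) was lower. Among the 9 testable lists of other cell types, none was called, and Ikzf2, which codes for Helios (-0.70), was the member of these lists that passed.

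Genes of cell division and of central metabolism were not called between the genotypes after stimulation. No gene passed among 24 DNA replication genes (median 0.02), 25 mitosis genes (-0.045), 18 glycolysis genes (-0.02), 27 oxidative phosphorylation genes (0.06), 19 cholesterol synthesis genes (0.03) or 17 hypoxia response genes (-0.07), and limma gave 0 calls in these lists when adjusted over the list alone as well. Across all genes 2289 had an unadjusted p under 0.05.

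The number of genes that passed at day 3 differed between fits. It was 689 with the day 3 arrays alone and 1306 with weights for array quality, 563 without Batf-/- naive replicate 1, 159, 135 and 152 without wild-type day 3 replicates 1, 2 and 3, and 122, 128 and 144 without Batf-/- day 3 replicates 2, 3 and 4. The calls of Erdr1, P2ry14 and Zfp365 were lost in 8, 7 and 6 of the fits that left out an array.

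The comparison of the genotypes in naive cells asks what differed before stimulation. Naive Batf-/- preparations had more RNA for receptors of natural killer cells and for B cell genes. Among the higher genes were the Ly49 receptors Klra7 (1.85 ± 0.30) and Klra8 (1.53 ± 0.17), the B cell scaffold gene Bank1 (3.76-fold, 1.91 ± 0.21, adjusted p = 0.00091) and the antibody light chain genes Igkv6-14 (2.02 ± 0.26) and Igkv9-120 (1.69 ± 0.27). Also higher were Ccr2 (1.53 ± 0.23) and the interferon-induced GTPase Iigp1 (1.83 ± 0.27). Lower, besides Batf, were Qpct (-1.26 ± 0.21), which codes for an enzyme that modifies the N-terminus of peptides, and the methionine salvage enzyme gene Adi1 (-0.91 ± 0.10; log2 ± SE, n = 3 and 2 throughout).

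In naive cells 196 genes passed, 148 higher and 48 lower in Batf-/-, of which 56 changed at least 2-fold, 49 higher and 7 lower. The other named genes that were higher were Abi3bp (2.56), Apol11b (2.55), Hepacam2 (1.58), Rnf157 (1.54) and Cyp4f18 (1.54). The others that were lower were Ttc28 (-1.16), Gpr34 (-1.12), the noncoding RNA Snhg14 (-1.11), the receptor tyrosine kinase gene Ltk (-1.03), the ion channel gene Cnga1 (-1.01), Zfp827 (-0.89), the T cell receptor gene Trbv13-2 (-0.88), Akap5 (-0.86) and Clps (-0.69). Abi3bp, Apol11b, Igkv6-14, Klra7, Hepacam2, Cyp4f18, Klra8, Gpr34, Snhg14 and Akap5 lay among the dimmest 40% of probe sets by their mean over all arrays. Near the background were the wild-type naive means of Abi3bp, Apol11b, Klra7, Cyp4f18 and Klra8, and the Batf-/- naive means of Gpr34, Akap5 and Clps, so these differences are lower bounds, while for Snhg14 both means were near it and the size has no reading. For the mean over all probe sets of the gene, the difference was smaller for Klra7 (0.935), Igkv9-120 (0.63), Rnf157 (0.66), Cyp4f18 (0.87), Ttc28 (-0.75), Snhg14 (-0.44), Zfp827 (-0.59) and Akap5 (-0.32). Of these Klra7, Rnf157 and Cyp4f18 still passed, and Igkv9-120 did not (adjusted p = 0.0724), nor did Clps. Of the fits that left out 1 of the 13 arrays, the call was lost in 11 for Ttc28 and Ltk, 10 for Zfp827 and Trbv13-2, 8 for Akap5 and 5 for Clps. Adi1 had 3 probe sets, and 1 of them passed in the opposite direction. Without overlap between the 5 arrays were 4466 genes, or 24.5%, where chance gives 20%.

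Of 13 measured NK cell receptor genes, 4 rose and 9 did not pass (9 rose and 1 fell when adjusted over the list alone). Besides Klra7 and Klra8 these were Klre1 (1.37) and Klrk1 (1.11). The list median was 0.97 (camera, adjusted p = 8.05e-09), and the call held with an estimated correlation (adjusted p = 0.00315). All 5 measured markers of the NK cell list belong to these 13 genes, and their mean log2 intensity was 6.61 ± 0.13 (SD, n = 2) in wild-type and 7.74 ± 0.44 (n = 3) in Batf-/- naive arrays. Ncr1, Tyrobp and Fcer1g were highest in Batf-/- naive replicate 1 (7.13, 10.95 and 10.18), which also had the highest neutrophil mean. In replicate 2 (5.22, 9.23 and 8.59) they were close to wild-type naive replicate 1 (4.84, 9.20 and 8.55). Klra8 and Klre1 were higher than wild type in every Batf-/- naive array.

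Markers of other cell types moved with the genotype in the naive preparations. Of 10 B cell markers 3 were higher, Cd22 (1.29), Cr2 (0.90) and Ebf1 (0.68), and 5 when adjusted over the list alone (median 0.53, adjusted p = 1.56e-07, or adjusted p = 0.0415 with an estimated correlation). Of 5 plasma cell markers Tnfrsf17 (1.20) was higher, and 4 when adjusted over the list alone (median 0.52, adjusted p = 2.99e-05, or adjusted p = 0.0353 with an estimated correlation). The mean of the B cell list was 7.06 ± 0.29 in wild-type and 7.65 ± 0.25 in Batf-/- naive arrays. The dendritic cell list was called without a member that passed (median 0.31, adjusted p = 0.00179, or adjusted p = 0.167 with an estimated correlation; 3 higher when adjusted over the list alone). The neutrophil list was called likewise (median 1.05, adjusted p = 0.0215, or adjusted p = 0.571 with an estimated correlation), but its mean was 9.13 in Batf-/- naive replicate 1 and 4.95 and 6.05 in replicates 2 and 3, against 5.87 and 5.46 in wild type, and without replicate 1 its median was -0.08. That call was also lost without wild-type naive replicate 2 (median 0.666, adjusted p = 0.129) and with weights for array quality (median 0.309). Lists of CD4 T cell, monocyte and macrophage, platelet, and stroma and endothelium markers were not called.

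Genes of sterol synthesis and of effector T cells were also higher in naive Batf-/- arrays. Of 19 cholesterol synthesis genes 4 rose, Cyp51 (0.775), Sqle (0.72), Fdps (0.64) and Idi1 (0.61), and 13 when adjusted over the list alone (median 0.26, adjusted p = 2.91e-10, or adjusted p = 0.0741 with an estimated correlation). Among 16 effector transcription factors Bhlhe40 (1.08), Xbp1 (0.82) and Irf4 (0.76) were higher and Myc (-0.45) was lower, with 6 higher and 1 lower when adjusted over the list alone (median 0.25, adjusted p = 0.0056, or adjusted p = 0.0741 with an estimated correlation). Of 8 type 17 genes the interleukin 1 receptor gene Il1r1 (1.36), Tmem176b (1.21) and Tmem176a (1.17) rose, and 4 rose and 1 fell when adjusted over the list alone (median 0.77, adjusted p = 1.98e-05, or adjusted p = 0.0741 with an estimated correlation). Interferon gamma, Ifng (0.745), passed among 24 cytotoxic genes, while Gzma was at 1.14 without passing (median 0.10, adjusted p = 0.00181, or adjusted p = 0.0836 with an estimated correlation; 6 higher when adjusted over the list alone). For the mean over all probe sets of the gene, Cyp51 (0.39), Fdps (0.30) and Irf4 (0.36) did not pass, nor did Aldoc and Cd200r1, named below, and Il1r1 was at 0.73.

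A further 6 lists were called in naive cells without holding with an estimated correlation. Inhibitory receptors stood higher (2 of 16 rose, Cd200r1 at 0.58 and Cd274 at 0.37; adjusted p = 0.00917, or adjusted p = 0.149 with an estimated correlation). So did AP-1 factors (0 of 15 passed; adjusted p = 0.00145, or adjusted p = 0.28 with an estimated correlation), glycolysis genes (1 of 18 rose, Aldoc at 1.04; adjusted p = 0.000557, or adjusted p = 0.359 with an estimated correlation) and genes of the unfolded protein response (0 of 16 passed; adjusted p = 8.01e-05, or adjusted p = 0.28 with an estimated correlation). Naive and memory T cell genes (median -0.19, adjusted p = 0.00016, or adjusted p = 0.449 with an estimated correlation) and genes of the T cell receptor complex (median -0.17, adjusted p = 0.00118, or adjusted p = 0.675 with an estimated correlation) stood lower, and no member of either passed. The calls of glycolysis genes and of the T cell receptor complex were lost without Batf-/- naive replicate 1, where the median of the latter was 0.008. The T cell receptor complex was also lost without wild-type naive replicate 1, and inhibitory receptors without wild-type naive replicate 2 and without Batf-/- naive replicate 2.

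**Figure D2:**
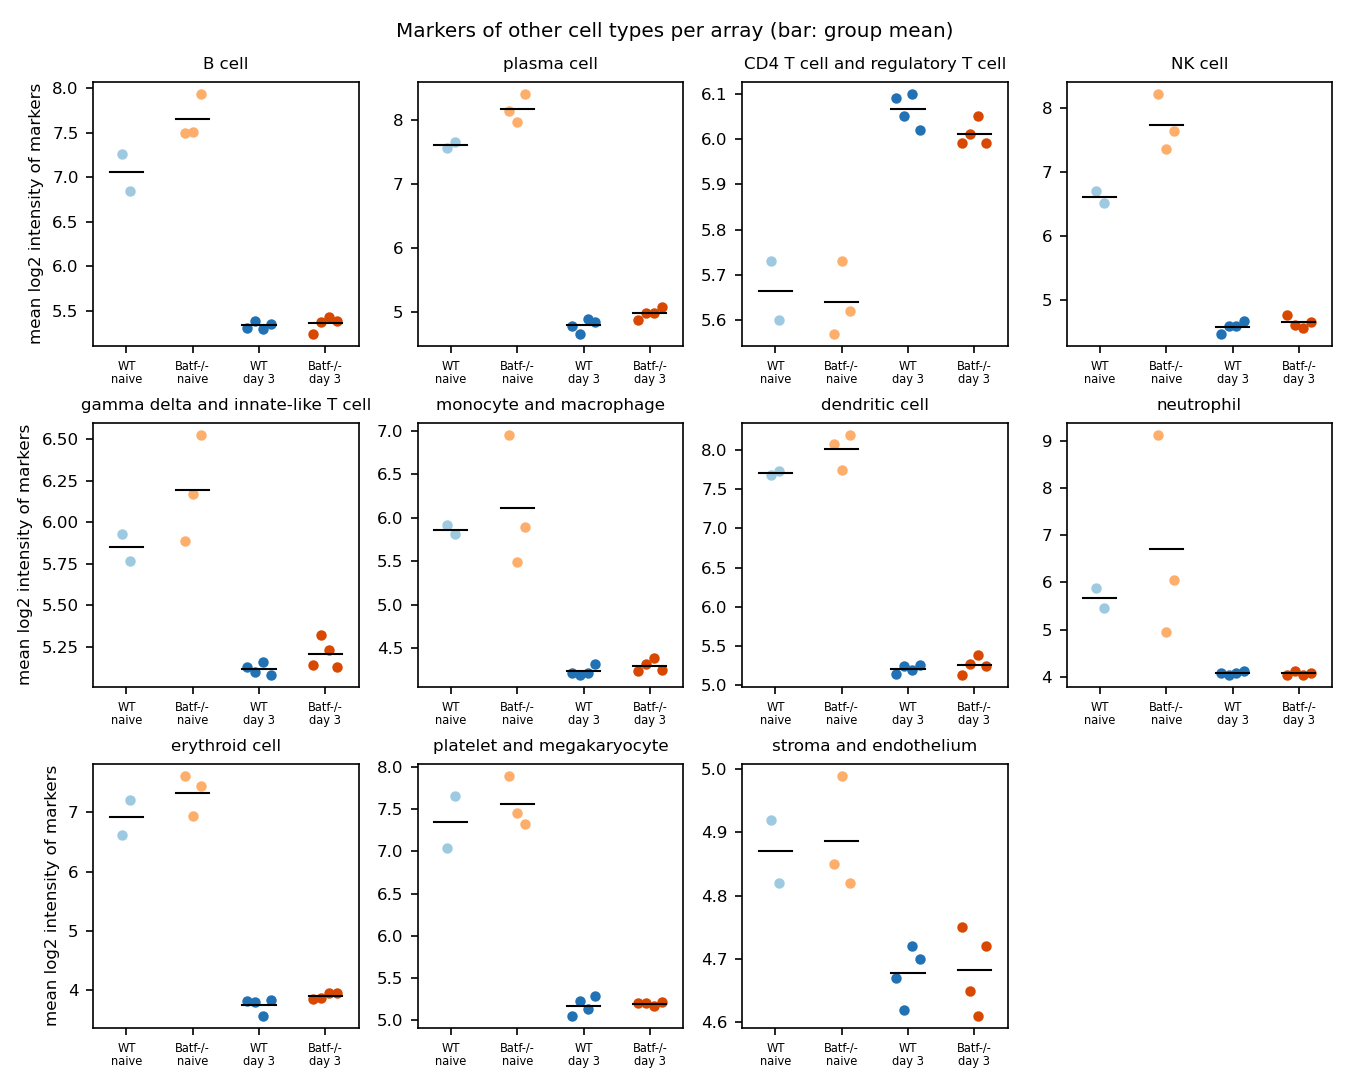
Mean log2 intensity of the markers of 11 other cell types in each array, by group (points, arrays; bars, group means). Naive arrays held more of most lists than day 3 arrays, and the neutrophil list stood at 9.13 in Batf-/- naive replicate 1.

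The number of genes that passed in naive cells differed between fits as well. With the 5 naive arrays alone, and thus with their own spread, 1 gene passed, Batf, and with weights for array quality 459 did. The count was 124 and 97 without wild-type naive replicates 1 and 2, 313, 627 and 114 without Batf-/- naive replicates 1, 2 and 3, 130, 124 and 120 without wild-type day 3 replicates 1, 2 and 3, and 119 and 128 without Batf-/- day 3 replicates 2 and 3.

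Few genes passed between the genotypes in both states. The naive comparison recovered fewer simulated changes of 0.5 log2 (48.5% against 79.2% at day 3), although the simulation gave both states the same spread. A gene that passed at day 3 alone can therefore still differ in naive cells. Itgae did not pass there, with naive means of 10.49 in wild type and 9.37 in Batf-/-, while those of Batf3 were 6.39 and 6.38. Of the 148 genes higher in naive Batf-/- cells 8 were also higher at day 3, Ccr2, Farp1, Ifng, Luzp1, Mid1, Ms4a6d, Tnfsf8 and Vcpkmt, where independent lists would share 0.984. Of the 48 lower genes 4 were also lower at day 3, Adi1, Batf, Efcab7 and Pde3b, where independent lists would share 0.34. Emp1, Klrk1 and Ttc39c were higher in naive and lower in stimulated Batf-/- cells. Luzp1, Ms4a6d, Farp1, Efcab7 and Pde3b were singled out after their values were seen. Across genes the 2 genotype effects had a Pearson r of 0.099 and a Spearman rho of 0.104, and r was 0.084 without Batf. Genes are not independent replicates. In 100 simulated sets without a genotype effect r lay between -0.048 and 0.051. The simulated genes varied independently, so that range does not decide on the r of these arrays.

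The comparisons of day 3 with naive cells ask what stimulation changed in each genotype. No group was cultured without the antibodies, so stimulation stands here for the antibodies, IL-2 and the 3 days in culture together. In wild-type cells the inhibitory receptor Ctla4 (7.05 ± 0.13), granzyme B (Gzmb, 6.14 ± 0.15), the interleukin 2 receptor alpha chain (Il2ra, 5.36 ± 0.10) and the transcription factor Bhlhe40 (5.13 ± 0.13) rose together with genes of glycolysis and low oxygen, led by Aldoc (185-fold, 7.53 ± 0.15, adjusted p = 1.58e-12), Ak4 (6.22 ± 0.34), Bnip3 (5.52 ± 0.10) and Egln3 (5.35 ± 0.11). Genes of other blood cells fell, among them Jchain of plasma cells (-8.94 ± 0.13, adjusted p = 1.63e-13), H2-Aa of antigen-presenting cells (-7.15 ± 0.15), Lyz1 of myeloid cells (-6.77 ± 0.47) and Ppbp of platelets (-6.01 ± 0.26). So did the early response gene Fos (-6.22 ± 0.13) and Slc15a2 (-6.18 ± 0.22; log2 ± SE, n = 4 and 2 throughout).

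In wild-type cells 8259 of 18194 genes passed, 4082 higher and 4177 lower at day 3, and 2072 of them changed at least 2-fold. The other named genes were Plod2 (5.19), Fam183b (5.09), Tspoap1 (5.02) and P4ha2 (4.92), which rose, and the carbonic anhydrase genes Car1 (-7.99) and Car2 (-6.50), the antibody genes Iglv1 (-7.05), Igha (-6.04) and Igkv8-30 (-5.92), and Mpeg1 (-5.91), which fell. In Batf-/- cells 8546 genes passed, 4332 higher and 4214 lower, and 1854 changed at least 2-fold. Among them Aldoc (6.44 ± 0.13), Ctla4 (5.88 ± 0.11), Bnip3 (5.67 ± 0.09), Gzmb (5.67 ± 0.13), Ak4 (5.39 ± 0.30), Il2ra (5.18 ± 0.09) and the costimulatory receptor Tnfrsf9 (4.87 ± 0.16) rose, and Jchain (-9.15 ± 0.11), Lyz1 (-8.16 ± 0.41), H2-Aa (-7.47 ± 0.13), the B cell gene Ms4a1 (-6.65 ± 0.26), Fos (-6.39 ± 0.12) and Cybb (-6.32 ± 0.20) fell (log2 ± SE, n = 4 and 3). Near the background lay the naive means of Ctla4 in wild type and of Ak4 and Il2ra in both genotypes, and in wild type those of Plod2, Fam183b and P4ha2. The same holds at day 3 for Jchain, H2-Aa and Lyz1 in both genotypes, for Ppbp, Slc15a2, Car1, Iglv1, Igkv8-30 and Mpeg1 in wild type, and for Ms4a1 and Cybb in Batf-/- cells. These changes are lower bounds. For the mean over all probe sets of the gene, the changes in wild-type and Batf-/- cells were smaller for Ak4 (2.70 and 2.49), Lyz1 (-4.38 and -5.325) and the naive T cell gene Klf3 (-1.68 and -1.455), and in wild type for Slc15a2 (-2.15). Groups without overlap were seen for 10605 genes in wild type (58.3%, chance 13.3%) and 8776 in Batf-/- (48.2%, chance 5.71%).

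Cell division, glycolysis, sterol synthesis and the hypoxia response rose in both genotypes. In wild type all 25 mitosis genes rose, with Aurkb at 3.87 and Bub1 at 3.85, and in Batf-/- cells all 25 rose, with Bub1 at 3.48 and Nusap1 at 3.40 (medians 3.16 and 2.85, adjusted p = 1.22e-13 and 2.57e-13, or adjusted p = 0.285 and 0.276 with an estimated correlation). Of 24 DNA replication genes 23 rose in each genotype (adjusted p = 4.15e-09 and 5.8e-09, or adjusted p = 0.335 and 0.324 with an estimated correlation). Of 18 glycolysis genes 17 and 18 rose, such as hexokinase Hk2 at 4.34 and 3.89 (adjusted p = 3.24e-14 and 4.82e-14, or adjusted p = 0.0468 and 0.0485 with an estimated correlation). All 19 cholesterol synthesis genes rose in both, such as Cyp51 at 4.35 and 3.69 (adjusted p = 6.91e-20 and 2.92e-19, or adjusted p = 0.0416 and 0.0231 with an estimated correlation). Of 17 hypoxia response genes 16 rose and 1 fell in each (adjusted p = 2.12e-11 and 4.3e-11, or adjusted p = 0.0485 and 0.0562 with an estimated correlation).

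Naive T cell genes, interferon response genes and early response genes fell in both genotypes. Of 20 naive and memory genes 14 fell in wild type and 15 in Batf-/- cells, such as Klf3 at -2.75 and -2.43 (adjusted p = 3.08e-06 and 5.64e-06, or adjusted p = 0.285 and 0.276 with an estimated correlation). Of 22 type I interferon response genes 20 and 19 fell, such as Ifit1 at -4.23 and -3.34 (adjusted p = 9.61e-11 and 1.86e-09, or adjusted p = 0.127 and 0.136 with an estimated correlation). Of 23 early T cell receptor response genes 17 and 18 fell, such as Egr1 at -3.63 and -2.81 (adjusted p = 4.71e-06 and 2.28e-06, or adjusted p = 0.0468 and 0.0421 with an estimated correlation). Of 23 ribosome biogenesis genes 21 and 17 fell, such as Utp20 at -1.72 and -1.23 (adjusted p = 3.9e-08 and 6.73e-07, or adjusted p = 0.108 and 0.136 with an estimated correlation). Of 13 NK cell receptor genes 9 and 11 fell (adjusted p = 0.00486 and 7.59e-07, or adjusted p = 0.0485 and 0.0117 with an estimated correlation), although Klrk1 rose by 1.95 in wild type. The effector transcription factors rose, 10 and 11 of 16 (adjusted p = 0.0018 and 0.00768, or adjusted p = 0.0468 and 0.0715 with an estimated correlation).

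Of 31 program lists, 17 were called in wild type and 15 in Batf-/- cells, and 6 and 4 of these also with an estimated correlation. Lists of B cell, plasma cell, NK cell, monocyte and macrophage, dendritic cell and platelet markers fell in both genotypes, and the neutrophil list fell in Batf-/- cells. Of these 13 calls the NK cell list in Batf-/- cells held with an estimated correlation (adjusted p = 0.0207). At day 3 the list means were 5.34 and 5.36 for B cell and 4.08 and 4.07 for neutrophil markers in wild-type and Batf-/- arrays, and 5 of 10 B cell markers, among them Ighm, were still above the background.

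**Figure D3:**
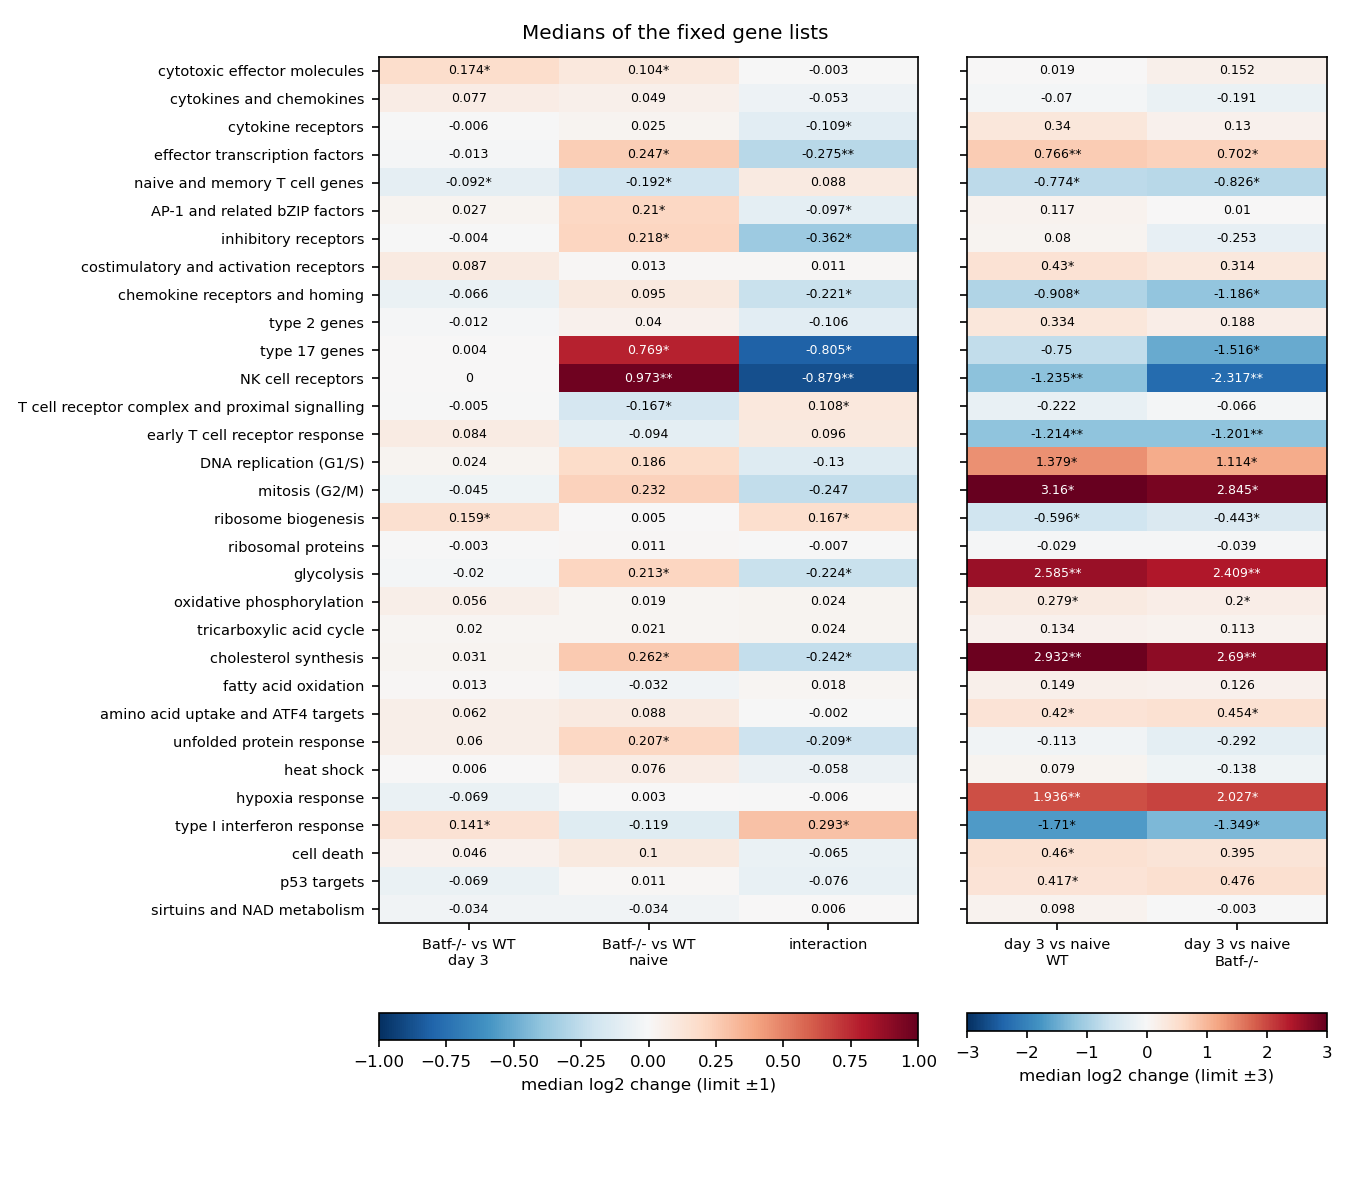
Median log2 change of the 31 program lists in each comparison (colour and printed value; single asterisk, called by camera; double asterisk, also with an estimated correlation). Mitosis, glycolysis and cholesterol synthesis genes rose in both genotypes, while medians between the genotypes at day 3 stayed close to 0.

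The change from naive to day 3 cells was largely shared by the genotypes. It includes the loss of RNA of other blood cells, such as Jchain and H2-Aa, so the values below do not measure the response of T cells alone. Of the genes that rose, 3244 rose in both, where independent lists would share 972, and 3557 fell in both, where independent lists would share 967. The opposite direction was called for 11 genes that rose in wild-type and fell in Batf-/- cells, among them Klrk1, Alcam, Casp1 and Ttc39c, and for 8 that did the reverse, among them Arhgap5 and Clps. Across genes the 2 responses had a Pearson r of 0.945 and a Spearman rho of 0.861, and genes are not independent replicates. Among genes that changed at least 4-fold in 1 part of the wild-type arrays, the response in Batf-/- cells reached a median share of 0.937 of the response in the remaining wild-type arrays. It was 0.911 for genes that rose and 1.015 for genes that fell, but 0.918 and 0.91 when genes with at least a 2-fold change were chosen, and the 2 ways to divide the arrays gave 0.958 and 0.915. The genes that fell include markers of other cells that stood higher in naive Batf-/- arrays, such as Jchain.

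The interaction asks which genes respond differently to stimulation without Batf. Klrk1 rose by 1.95 in wild-type cells and fell by 0.377 in Batf-/- cells, an interaction of -2.32 ± 0.19 (adjusted p = 0.000352). Thyroglobulin (Tg) rose by 3.59 in wild type and 1.16 in Batf-/- cells (-2.43 ± 0.24), Gpld1 by 2.87 and 0.90 (-1.97 ± 0.31), and Alcam changed by 1.5 and -0.49 (-1.98 ± 0.25). Slc15a2 fell by 6.18 in wild type but by 2.73 in Batf-/- cells (3.45 ± 0.30), and Ccr9 fell by 5.88 and 4.44 (1.44 ± 0.22). The wild-type day 3 mean of Slc15a2 (4.06) was near the background, so its fall of 6.18 and its interaction are lower bounds, and Tg (4.3 in wild type) and Gpld1 (4.50 and 4.51) had naive means near it. For the mean over all probe sets of the gene, Slc15a2 fell by 2.15 in wild type and its interaction was 1.19, while Ccr9 changed by -3.89 and -2.875. Batf3 (-1.11), Ctla4 (-1.18), Tnfrsf4 (-0.99) and Il7r (-0.91) had negative interactions and were lower in Batf-/- cells at day 3, with differences in naive cells of -0.01, 0.47, -0.05 and -0.16 that did not pass.

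In the interaction 118 genes passed, 30 with a positive and 88 with a negative value, and 54 had an effect of at least 2-fold. Of these 118 genes 52 also passed between the genotypes at day 3, 56 in naive cells, 3 of them in both, and 13 in neither. Among the named genes with a negative interaction, Abi3bp (-2.55), Igkv6-14 (-2.05), Bank1 (-1.86), S100a6 (-1.60) and the inflammatory caspase gene Casp1 (-1.52) were higher in naive Batf-/- cells and did not pass at day 3, whereas Ttc39c (-1.75) and Emp1 (-1.61) passed in both states. As3mt (-1.55) was also negative. The other named genes with a positive interaction were Erdr1 (3.13), Upp1 (1.45), Qpct (1.43), Cnga1 (1.39), Morc1 (1.15), Arhgap5 (1.07), Rab11fip2 (0.90), Dleu7 (0.82), Stag3 (0.80) and Spred2 (0.80). For Abi3bp, Igkv6-14 and Qpct both day 3 means were near the background, so their interaction has no measured level at day 3 behind it. At least 1 group mean near it was also seen for Upp1, Morc1, Dleu7, Stag3, Emp1 and As3mt. For the mean over all probe sets of the gene, it was smaller for Erdr1 (1.915), Ttc39c (-0.67) and Emp1 (-0.83), and Abi3bp, Arhgap5, Rab11fip2 and Spred2 did not pass, nor did Fdps and Cyp51, named below. In the fits that left out 1 of the 13 arrays, the call was lost in 12 for Abi3bp, 10 for Qpct, 9 for Rab11fip2, Stag3 and Spred2, 6 for Upp1 and 5 for Arhgap5.

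The interaction was negative for effector transcription factors, with Bhlhe40 (-1.09) and, in the opposite direction, Myc (0.70) among 16 (median -0.28, adjusted p = 0.000327, and adjusted p = 0.0347 with an estimated correlation). It was also negative for NK cell receptor genes, with Klrk1 and Klra8 (-1.48) among 13 (median -0.88, adjusted p = 1.46e-09, and adjusted p = 0.00203 with an estimated correlation). Of these 13 genes 6, among them Klra8, had day 3 means near the background in both genotypes, so their interaction has no measured level at day 3 behind it. Bhlhe40 rose by 5.13 and 4.04, with differences of 1.08 and -0.01. Of 19 cholesterol synthesis genes 4 had a negative interaction, Fdps (-0.68), Cyp51 (-0.65), Sqle (-0.63) and Idi1 (-0.58), the 4 that stood higher in naive Batf-/- cells (adjusted p = 9.03e-08, or adjusted p = 0.128 with an estimated correlation). Inhibitory receptors (median -0.36, adjusted p = 0.000327, or adjusted p = 0.0726 with an estimated correlation) and type 17 genes (median -0.80, adjusted p = 4.26e-05, or adjusted p = 0.0827 with an estimated correlation) were also negative. The medians of these 5 lists between the genotypes lay between 0.218 and 0.973 in naive cells and between -0.013 and 0.031 at day 3. Markers of other cell types moved likewise, with interaction medians of -1.08 for NK cell (adjusted p = 1.94e-05, and adjusted p = 0.0112 with an estimated correlation), -0.45 for B cell (adjusted p = 4.91e-06, or adjusted p = 0.108 with an estimated correlation) and -1.05 for neutrophil markers (adjusted p = 0.038, or adjusted p = 0.694 with an estimated correlation). Both day 3 means were near the background for 2 of the 5, 5 of the 10 and 7 of the 8 markers. The neutrophil median was 0.137 without Batf-/- naive replicate 1. In all 13 of the 31 lists were called, 3 with a positive and 10 with a negative median, and 2 of the 13 held with an estimated correlation, the effector transcription factors and NK cell receptors. The count of genes was 542 with weights for array quality, 270 and 283 without Batf-/- naive replicates 1 and 2, 72, 66 and 62 without wild-type day 3 replicates 1, 2 and 3, and 58, 60 and 62 without Batf-/- day 3 replicates 2, 3 and 4.

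**Figure D4:**
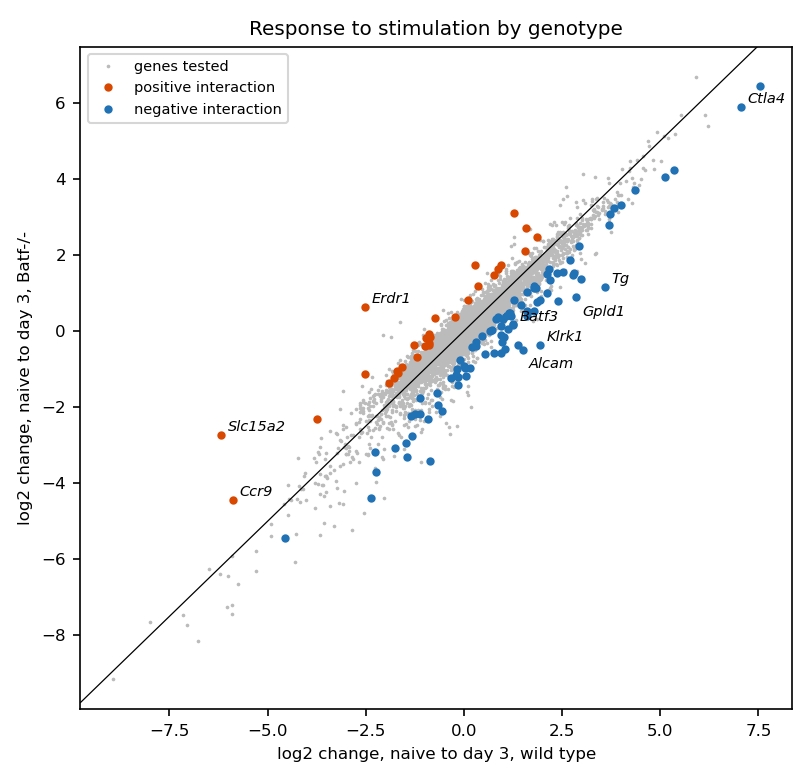
Log2 change from naive to day 3 of each gene in wild-type (x axis) and Batf-/- cells (y axis), with the line of equality and the 118 genes of the interaction in colour. The genes lay along the line (Pearson r 0.945), with Slc15a2 above it and Klrk1 and Tg below it.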

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

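The tests of cell sources and of a smaller response were chosen after the results were seen, whereas the regroupings of arrays and the rules for outlying arrays and for differing effects were set beforehand.

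Between the genotypes at day 3, 1 of 35 splits of the 8 arrays into 4 and 4, the real one, called as many as the 250 genes. The highest count of the others was 0. Chance is therefore an unlikely source of that number, although 1 of 35 is the smallest share that these splits can give. In the other splits the genotype effect adds to the spread, which lowers their counts. The splits also do not tell the genotype from another difference between the cultures of the groups. A smaller response to stimulation, tested as the source of the 250 genes, would make the day 3 difference opposite to the wild-type response, as it was for 159 of them (63.6%, exact 95% interval 57.3 to 69.6), a count that the shared wild-type day 3 arrays tend to raise. The interval treats genes as independent, which they are not, so it does not measure the spread between arrays. The other 91 genes differed at day 3 in the direction of their wild-type change, so a smaller response alone does not account for all 250. That direction does not make their response larger. It also counts genes that already differed in naive cells, such as Batf. Genes with little wild-type change count too, such as Vcpkmt (wild-type means of 7.93 in naive cells and 8.0 at day 3). Across all genes, with the wild-type day 3 arrays divided between the effects, r was -0.039 and -0.12, and between -0.138 and -0.015 over the 6 ways to divide them, so a small shortfall stays open. The test on the 250 genes was added after that r was seen. Open as well is a direct role of Batf at single genes, which was not tested.

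The 148 genes higher in naive Batf-/- cells were weighed as another pattern. Myeloid cells in Batf-/- naive replicate 1, where 8 of 8 neutrophil markers were highest, were tested as their source. A fit without that array called 213 genes higher, 133 of the 148 among them, so that array alone does not account for most of the 148. The count of 213 decides little by itself, since the day 3 count rose from 250 to 563 in the same fit. The median excess of the 148 genes over wild type was 0.83, 0.70 and 0.87 in replicates 1, 2 and 3, on which they were chosen. More B-lineage RNA in the Batf-/- preparations may account for part of them, as all 15 B cell and plasma cell markers had a higher mean, 9 of them without overlap of the arrays. Of the 15, 11 were highest in Batf-/- naive replicate 3. The B cell mean was 7.50, 7.51 and 7.94 in the Batf-/- and 7.26 and 6.85 in the wild-type naive arrays. Both lists had been called on these arrays before, so these counts are no separate test. Ighm was at 14.24 in wild-type and 14.50 in Batf-/- naive arrays, and Jchain at 12.59 and 13.18. The magnetic selection is meant to remove such cells, but naive arrays of both genotypes held this RNA, with Jchain at 3.64 and 4.03 at day 3. Whether RNA of other cells accounts for all 148 cannot be told apart from a change within T cells. Of the 148, 73 (49.3%, exact 95% interval 41 to 57.7) fell with stimulation in Batf-/- cells, against 34.3 for independent lists, as most lists of other cell types did. The shared Batf-/- naive arrays tend to raise that count. In wild-type cells 36 of them fell (24.3%, exact 95% interval 17.7 to 32.1), a count that the shared wild-type naive arrays tend to lower, so neither decides. Both intervals treat genes as independent, which they are not. T cells that had already responded or that carry a memory state may contribute, since 51 of the 148 rose with stimulation in Batf-/- cells against 35.2 for independent lists, although the shared naive arrays tend to lower that count. In wild-type cells 77 rose against 33.2, where the shared naive arrays tend to raise the count. Falls in Batf-/- cells exceeded independent lists by more than rises did, so the rises are weak evidence for such T cells. Among the 51 are Irf4, Bhlhe40, Cd44, Ifng and Cyp51. For the mean over all probe sets of the gene, the naive differences of Irf4 (0.36), Cd44 (0.34) and Cyp51 (0.39) did not pass.

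Between naive and day 3 Batf-/- cells, 1 of 35 splits of the 7 arrays, the real one, called as many genes as the real 8546. The highest of the others was 4311. Chance is an unlikely source of that number, but 1 of 35 is the smallest share that these splits can give. Each other split mixes the states in at least 1 part, so the stimulation effect adds to its spread and lowers its count. For program lists chance is not excluded at day 3, where 11 of 35 splits called as many as the real 4 lists, with up to 6 in the others, among them 4 of the 18 splits with equal shares of the genotypes. Between naive and day 3 Batf-/- arrays 11 of 35 splits called as many lists as the real 15, with up to 18, but no split of 7 arrays has equal shares of naive and day 3 arrays. Each carries part of the stimulation effect, so this count decides nothing on the lists. All 25 mitosis and all 19 cholesterol synthesis genes passed in Batf-/- cells, as they did in the wild-type arrays.

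Some arrays stood far from the other 3 of their group, by the ratio of the gap to the range. Of 254 sets of 4 values 17 did so (critical value 0.829), where chance gives about 5%. Among genes these were Rpl39l in wild-type day 3 replicate 2 (0.875), Gzmb (1.0) and As3mt (0.921) in replicate 3, and Bnip3 (0.862), Plod2 (0.833), Iglv1 (0.873) and Stag3 (0.921) in replicate 4. In Batf-/- day 3 arrays they were Itgae (0.843) and Tspoap1 (0.857) in replicate 1 and Igha (0.897) in replicate 3. Among list means they were inhibitory receptors (0.859), glycolysis (0.833) and the unfolded protein response (0.924) in wild-type day 3 replicate 4, erythroid cell markers (0.887) in wild-type replicate 3, the T cell receptor complex (0.927) and p53 targets (0.887) in Batf-/- replicate 1, and ribosome biogenesis (0.833) in Batf-/- replicate 2. The range of Gzmb over the 4 arrays was 0.04.

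The genotype effect differed between naive and day 3 cells for 118 genes by the interaction test. It was higher at day 3 for Slc15a2 (3.45), Erdr1 (3.13), Upp1 (1.45), Ccr9 (1.44), Qpct (1.43), Cnga1 (1.39), Morc1 (1.15), Arhgap5 (1.07), Rab11fip2 (0.90), Dleu7 (0.82), Stag3 (0.80), Spred2 (0.80) and Myc (0.70). It was lower for Abi3bp (-2.55), Tg (-2.43), Klrk1 (-2.32), Igkv6-14 (-2.05), Alcam (-1.98), Gpld1 (-1.97), Bank1 (-1.86), Ttc39c (-1.75), Emp1 (-1.61), S100a6 (-1.60), As3mt (-1.55), Casp1 (-1.52), Klra8 (-1.48), Ccr1 (-1.46) and Cd22 (-1.42). It was also lower for Tmem176b (-1.30), Il1r1 (-1.28), Ctla4 (-1.18), Batf3 (-1.11), Egln3 (-1.11), Bhlhe40 (-1.09), Aldoc (-1.09), Tmem176a (-1.08), Tnfrsf4 (-0.99), Il7r (-0.91), Fdps (-0.68), Cyp51 (-0.65), Sqle (-0.63) and Idi1 (-0.58).

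Called lists in the interaction had negative medians for NK cell receptors (-0.88), type 17 genes (-0.80), inhibitory receptors (-0.36), effector transcription factors (-0.28), cholesterol synthesis (-0.24), glycolysis (-0.22), chemokine receptors and homing (-0.22), the unfolded protein response (-0.21), cytokine receptors (-0.11) and AP-1 factors (-0.10). Medians were positive for the type I interferon response (0.29), ribosome biogenesis (0.17) and the T cell receptor complex (0.11). Of these 13 calls NK cell receptors and effector transcription factors held with an estimated correlation, and the other 11 had an adjusted p between 0.0726 and 0.743 with it. Cell type lists that were called were NK cell (-1.08), neutrophil (-1.05), B cell (-0.45), plasma cell (-0.31) and dendritic cell (-0.27). Of these 5 the NK cell list held with an estimated correlation, the others had an adjusted p between 0.108 and 0.694 with it, and the neutrophil median was 0.137 without Batf-/- naive replicate 1.

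Among 10092 probe sets without a single gene name, which no comparison used, 29 passed at day 3 (15 higher and 14 lower in Batf-/-), 82 in naive cells (26 higher and 56 lower) and 10 in the interaction.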

How the results depend on the processing

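The alternatives were set beforehand. Of the genes named by rule, all 24 in each stimulation comparison, 21 of 24 at day 3 and 12 of 24 in the interaction stayed past the threshold in the alternatives run, as did 1 of 24, Batf, between naive cells, and none of the named genes reversed. The naive comparison of 3 and 2 arrays is limited by the spread of the naive arrays, whose log2 differences had an SD of 0.222 to 0.42 within Batf-/- and 0.234 within wild type, against 0.147 to 0.196 at day 3. Dim probe sets limit what their intensity can show over the background. Counts of genes are given in the order day 3, naive and interaction. Array quality weights gave 1306, 459 and 542, and the compared groups alone gave 689 and 1. That naive fit has 3 residual degrees of freedom and takes its spread from the naive arrays alone. A minimum of 2-fold gave 30, 56 and 54, and 2072 and 1854 for stimulation in wild type and Batf-/-, by its construction. Leaving out single arrays gave 122 to 563, 97 to 627 and 58 to 283. The lowest came without Batf-/- day 3 replicate 2, wild-type naive replicate 2 and Batf-/- day 3 replicate 2, and the highest without Batf-/- naive replicate 1, replicate 2 and replicate 2. The cause was not tested. A fit that leaves 1 wild-type naive array assumes that it varies like the other groups.

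Replicate numbers as a block gave 125, 87 and 50, of which 124, 85 and 48 had been called without it. Of 16 pairs of arrays with the same number 0 had deviations that correlated above 0.1 (-0.258 to 0.05), so the numbers do not pair the arrays.

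Program lists called with an estimated correlation numbered 0 at day 3, 1 in naive cells, 6 and 4 for stimulation in wild type and Batf-/-, and 2 in the interaction. With fry they numbered 28 and 29 for stimulation and 5 in the interaction. Fry does not compare a list with other genes. Cell type lists numbered 3, 0, 1 and 1 with an estimated correlation (naive, wild-type and Batf-/- stimulation, interaction), 3, 3, 4 and 2 without the dim 40% of probe sets, where 4 of the 9 lists could be tested, and 2 in the interaction with fry. Leaving out arrays gave 11 to 17 program lists in naive cells, the highest without Batf-/- naive replicate 1, and 3 to 6 cell type lists in the interaction. The neutrophil list reversed without Batf-/- naive replicate 1, to -0.077 in naive cells (range -0.077 to 1.873) and 0.137 in the interaction (range -1.787 to 0.137). The T cell receptor complex list had a median of 0.008 in naive cells without that array. With the mean of all probe sets, Sparc (-0.23) and Ndufb8 (-0.057) reversed in wild-type stimulation. The share of the response was 0.931 without dim probe sets, 0.915 for genes with a 2-fold change, and 0.891 to 0.989 when arrays were left out. The cause was not tested. The correlation of the genotype effects stayed within its spread.

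Robust eBayes was not run for lists, since camera has no such option. The interaction needs every group, so no fit to the compared groups alone was run, and the share was not run without a wild-type naive array, since each part needs 1.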

Other observations

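The hypothesis on the chromosome of Batf and its tests were chosen after the results were seen.

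Further gene lists were called between naive and day 3 cells, some in 1 genotype. Targets of p53 were called in wild type, where 6 of 13 rose and 2 fell, led by the cell cycle inhibitor Cdkn1a (4.61 in wild type and 4.22 in Batf-/-; adjusted p = 0.03 and 0.0877, or adjusted p = 0.335 and 0.441 with an estimated correlation). Of 22 genes of amino acid uptake and of the stress factor Atf4, 13 rose in each genotype, such as Trib3 (3.91 and 3.56) and Psat1 (2.12 and 1.85; adjusted p = 0.0157 and 0.00562, or adjusted p = 0.366 and 0.324 with an estimated correlation). Of 27 oxidative phosphorylation genes 17 and 16 rose by small amounts (medians 0.28 and 0.20; adjusted p = 0.0157 and 0.00616, or adjusted p = 0.536 and 0.441 with an estimated correlation). Of 17 costimulatory receptors 9 rose in each, such as Tnfrsf9 (4.72 and 4.87; adjusted p = 0.03 and 0.0791, or adjusted p = 0.343 and 0.441 with an estimated correlation). Of 16 cell death genes 10 rose in each, such as Bcl2l1 (1.0 and 1.26; adjusted p = 0.0355 and 0.0523, or adjusted p = 0.127 and 0.136 with an estimated correlation). Chemokine receptors and homing molecules fell, 13 and 15 of 23, such as Itga4 (-3.06 and -3.06; adjusted p = 0.00238 and 4.1e-05, or adjusted p = 0.285 and 0.136 with an estimated correlation), and type 17 genes were called in Batf-/- cells, where 6 of 8 fell (adjusted p = 0.00123, or adjusted p = 0.136 with an estimated correlation).

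Other lists were called in neither genotype, although members changed. Cytotoxic genes went both ways in wild type, with 9 of 24 rising and 7 falling, such as Gzmb (6.14) and Gzma (-3.40). Inhibitory receptors did likewise, with 7 of 16 rising and 6 falling, such as Ctla4 (7.05), Lag3 (3.70) and Klrg1 (-1.55). Among sirtuins and NAD metabolism 5 of 13 rose and 5 fell, such as Nampt (2.00), which codes for the enzyme that salvages nicotinamide. Of 22 cytokine receptors 11 rose and 8 fell, of 23 cytokines and chemokines 6 rose and 5 fell, and of 15 AP-1 factors 6 rose and 5 fell. Of 17 ribosomal protein genes 1 rose and 2 fell, of 14 genes of the tricarboxylic acid cycle 6 rose and 3 fell, and of 14 genes of fatty acid oxidation 6 rose and 5 fell. Of 12 heat shock genes 1 rose and 4 fell, of 16 genes of the unfolded protein response 4 rose and 6 fell, and of 17 genes of the T cell receptor complex 2 rose and 9 fell. Of 10 type 2 genes 5 rose, such as Ccr4 (0.76) and Il4ra (0.48).

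The lists with fewer than 5 measured genes had means of 5.85 ± 0.11 and 6.20 ± 0.32 for gamma delta T cells and 6.92 ± 0.42 and 7.33 ± 0.36 for erythroid cells in wild-type and Batf-/- naive arrays (SD, n = 2 and 3), and at most 5.32 and 3.95 in Batf-/- day 3 arrays.

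Donor-strain variants carried along with the Batf deletion were tested as a hypothesis. Batf lies on chromosome 12 (assembly GRCm38.p6), and 7 of the 47 other genes lower in naive Batf-/- cells lie there too, against 1.62 for chance (Fisher's exact test, two-sided, p = 0.00106, adjusted p = 0.0424 over 80 tests of chromosomes and directions). They are Adam6b, Adi1, Akap5, Ap4s1, Churc1, Coch and Fntb, which follow neither from the rule nor from a list and were chosen after their values were seen. A variant that acts in both states would keep the difference at day 3. Over all 7 genes, tested before any division, the median at day 3 was -0.021, and they were divided by their day 3 level after that value was seen. For the 4 genes above background at day 3 the median difference was -0.57 in naive cells, for which the genes were chosen, and -0.15 at day 3, with an SD of 0.27 over the genes. They went apart, with 0.03 for Ap4s1, -0.02 for Fntb, -0.55 for Adi1 and -0.28 for Churc1, so the median decides nothing, and for the 3 genes near background at day 3 (median 0.02) no value decides. Such variants therefore cannot be told apart from an effect of Batf. Adi1 and Churc1 lie 296 and 96 measured genes from Batf, and 1 of the 3 probe sets of Adi1 passed in the opposite direction in naive cells.

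On chromosome 6, which holds clusters of NK cell receptor and antibody light chain genes, lay 22 of the 147 genes higher in naive Batf-/- cells that have a chromosome, against 8.10 for chance (adjusted p = 0.00144, the same 80 tests). The Y-linked gene Eif2s3y had a log2 intensity of 9.50 or more and Xist, the transcript of the inactive X chromosome, of 4.66 or less in the 13 arrays.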
